A study of Homo sapiens with 16 samples.

How the data were processed

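RNA from ST486 cells, a Burkitt lymphoma line, was measured on 8 two-colour Agilent arrays of 1 slide. Cells had been infected with a lentivirus carrying 1 of 4 short hairpin RNAs. Per the labels, 2 hairpins were aimed at the long noncoding RNA KTN1-AS1 and 2 were non-targeting controls. Each array held 1 hairpin in 1 replicate, with the day 4 sample in Cy3 and the day 6 sample in Cy5, so that day and dye could not be told apart and no array exchanged the dyes. The 16 samples thus form 8 groups of 2, by hairpin and day. The replicate number was also the slide row (2) and the hairpin the slide column (4). The labels do not say whether the replicates were separate infections, so they may be technical replicates. A treatment note shared by all samples speaks of hairpins against MYC and a harvest on day 8, whereas the titles, the treatment labels and the series design give KTN1-AS1 and days 4 and 6. The latter were used.

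Median spot and median local background intensities, as deposited, are scanner brightness with no normalization. They were extracted with Agilent Feature Extraction 12.0.1.1, per the file headers. The processed intensities in the same files were background subtracted, spatially detrended and dye normalized within each array, per the file headers. The deposited value table is on a log2 scale and was quantile normalized over all 16 columns, as its identical column distributions showed. How the authors reached that table is not recorded. Its log2 values ran from 2.15 to 17.3, and each of its 16 columns correlated best with the channel it was labelled for (r across probes 0.772 to 0.980, slope 0.984 to 1.01).

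Local background was removed with the normexp method of limma 3.58.1 (R 4.3.3) with an offset of 50, channels were balanced by loess within each array, with no weight on control spots and spots marked as unusable by the extraction software, and arrays were scaled to each other with Aquantile. The plan had named mean spot signals, which the files do not hold, so median signals took their place. Spots of a probe were averaged. Of 62976 spots, 60901 were not controls and held 58201 probes. Gene symbols were looked up by RefSeq accession and name in a reference table of assembly GRCh38.p14, which gave 22439 symbols to 31104 probes and left 27097 probes under their own identifiers. The array was designed on build hg19, so no coordinates are given, and the files hold no probe sequences. Probes had to be well above background, by the extraction software's mark, in at least 4 of 16 channels, which 32205 were. A gene was represented by its brightest probe, which left 26762 features, 15668 of them with a symbol.

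Groups were compared with limma (lmFit and eBayes, two-sided) on log2 values with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Knockdown was compared with control over 4 arrays against 4, on the mean of both days, on day 4 and on day 6, with both hairpins of an arm counted as its replicates. The day difference of the knockdown effect was tested on each array's log2 ratio of day 6 over day 4. A probe's dye effect cancels between arms there only if it is the same at every signal level. Each knockdown hairpin was compared with both controls in a fit with 4 hairpin groups of 2 arrays. KTN1-AS1, KTN1 and MYC were also tested with an exact permutation test over the 70 arrangements of 8 arrays, two-sided, whose smallest p is 0.0286. The 35 gene lists, fixed before the data were examined, were tested with camera (preset correlation between genes 0.01), with camera and an estimated correlation, and with fry. They cover MYC targets, growth, cell cycle, stress, metabolism, B cell identity, interferon and other signalling, markers of other cell types, and the neighbours of KTN1-AS1 on chromosome 14. Choices of tests, lists and alternatives were made before the data were examined, except where the text says otherwise.

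Named genes followed a rule set before the data were examined. KTN1-AS1, KTN1 and MYC were always named. For the mean of both days, the 10 largest rises and 10 largest falls were named among genes past the threshold with a symbol and the same direction with each hairpin on each day. Day 4 and day 6 took the 3 largest each way by the same rule, and the other comparisons the 3 largest each way past the threshold, or the 3 smallest p where fewer than 3 passed. Gene lists gave up to 4 members with the smallest p. Whether replicate numbers pair the samples was checked from the values: the differences between replicates of any 2 hairpins correlated across genes with r from 0.300 to 0.369 over 6 pairs of hairpins, and replicate number was used as an alternative block.

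The fits were tested on simulated data, in which 200 of 26762 features were changed by known amounts. Each simulated value was drawn on its own, with the spread between replicates of a hairpin. Beyond the known changes, hairpins of an arm did not differ and no effect of array or replicate was shared. The recovered shares may therefore overstate recovery in the real data. For the mean of both days, 91.1% of changes of 0.5 log2 units and 97.2% of changes of 1 log2 unit were recovered. The recovered shares at 0.5 and 1 log2 units were 51.8% and 87.3% for day 4 and 78.6% and 97.2% for day 6. They were 66.1% and 91.5% for knockdown hairpin 1, and 60.7% and 95.8% for hairpin 2. For the day difference of the knockdown effect they were 23.3% and 77.9%, and for the difference between the knockdown hairpins 40.0% and 93.9%. Alternatives were Agilent's processed signals scaled by quantiles or to the 75th percentile, quantile normalization without loess, the authors' value table, no filter or a filter of 12 of 16 channels, the mean of a gene's probes, replicate number as a block, hairpin as a random block or fixed term, all 16 samples in 1 fit, and leaving out each array. Another 3 were added after the data were seen: day 6 samples only for the hairpin comparisons, leaving out both knockdown arrays of replicate 1, and naming the 5 largest differences each way between the knockdown hairpins at day 6. Figures were drawn with Python 3.11.15. Nothing was left out of the samples.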

Results

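Gene expression was measured in 16 samples of ST486, a Burkitt lymphoma cell line, on 8 two-colour arrays. Short hairpin RNAs against KTN1-AS1, a long noncoding RNA that the series title calls MYC-induced, were compared with non-targeting hairpins 4 and 6 days after infection. There were 2 KTN1-AS1 hairpins and 2 control hairpins, each with 2 replicates per day, which may be technical replicates. Day 4 samples, all in Cy3, had 49.3% to 61.3% of probes well above background, with median spot signals of 50 to 73 and median backgrounds of 22 to 25 scanner units. Day 6 samples, all in Cy5, had 36.6% to 51.2% of probes well above background, with median signals of 39 to 59 and backgrounds of 32 to 34. The 75th percentile of Agilent's processed signal lay between 199 and 335 in control samples and between 254 and 394 in knockdown samples. The number of arrays limits the precision, and the p values below measure spread between these samples, not between independent cultures beyond them.

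KTN1-AS1 was read by 2 probes, each tested among all probes. The dimmer probe (A_19_P00813554, NR_027123) averaged 7.10 ± 0.07 log2 units in the control arrays and 6.66 ± 0.37 in the knockdown arrays (SD, n = 4 each, mean of both days), a difference of −0.44 ± 0.15 (SE) that did not pass the test (adjusted p = 0.118, exact permutation p = 0.0857). The brighter probe (A_22_P00015864, NR_027123) averaged 8.99 ± 0.07 and 9.001 ± 0.10, a difference of 0.01 ± 0.06 (adjusted p = 0.953, exact permutation p = 0.971). At day 6 the dimmer probe read lower with hairpin 1 than in controls (log2 −0.61 ± 0.10, adjusted p = 0.00294), but it was not well above background in either hairpin 1 sample, so the size of this difference is uncertain. With hairpin 2 the difference was 0.03 ± 0.10 (adjusted p = 0.892), and the hairpins differed by −0.64 ± 0.12 (adjusted p = 0.00983). At day 4 the dimmer probe read 7.03 and 6.24 in replicates 1 and 2 labelled hairpin 1, and 6.13 and 7.13 in those labelled hairpin 2, against 7.21 to 7.31 in the controls. It was also not well above background in the day 4 sample of replicate 1 labelled hairpin 2 and in 1 control sample of day 6. With both hairpins pooled at day 4, the dimmer probe differed from controls by −0.60 ± 0.22 and did not pass the test (adjusted p = 0.21). The exact permutation p was 0.0286, the smallest this design can give. The brighter probe differed from the controls by −0.07 ± 0.09 with hairpin 1 and −0.0024 ± 0.09 with hairpin 2 at day 6. No file says which part of the transcript each probe reads or where the hairpins bind. As neither probe was lower with hairpin 2 at day 6, "knockdown" and hairpin numbers below mean the arrays labelled so.

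MYC, the transcription factor whose translocation drives Burkitt lymphoma, averaged 11.89 ± 0.03 log2 units in control arrays and 11.37 ± 0.37 in knockdown arrays (SD, n = 4 each, mean of both days). The difference of −0.52 ± 0.15 (SE) did not pass the test across genes (adjusted p = 0.0705, exact permutation p = 0.0286, the smallest this design can give), although all 4 knockdown arrays lay below every control array. That separation, and with it the permutation p, rests on a gap of 0.00015 log2 units between the highest knockdown array (hairpin 2 replicate 2) and the lowest control array. At day 6, MYC was 1.95-fold lower with hairpin 1 (log2 −0.97 ± 0.09, adjusted p = 1.6e-04), and with hairpin 2 the difference from controls was −0.04 ± 0.09 (adjusted p = 0.81, 95% confidence interval −0.23 to 0.15). The hairpins differed by −0.92 ± 0.10 (adjusted p = 7.9e-04 among probes). KTN1, the protein-coding gene beside KTN1-AS1, differed by −0.16 ± 0.10 between the arms (adjusted p = 0.406, exact permutation p = 0.20).

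**Figure D1:**
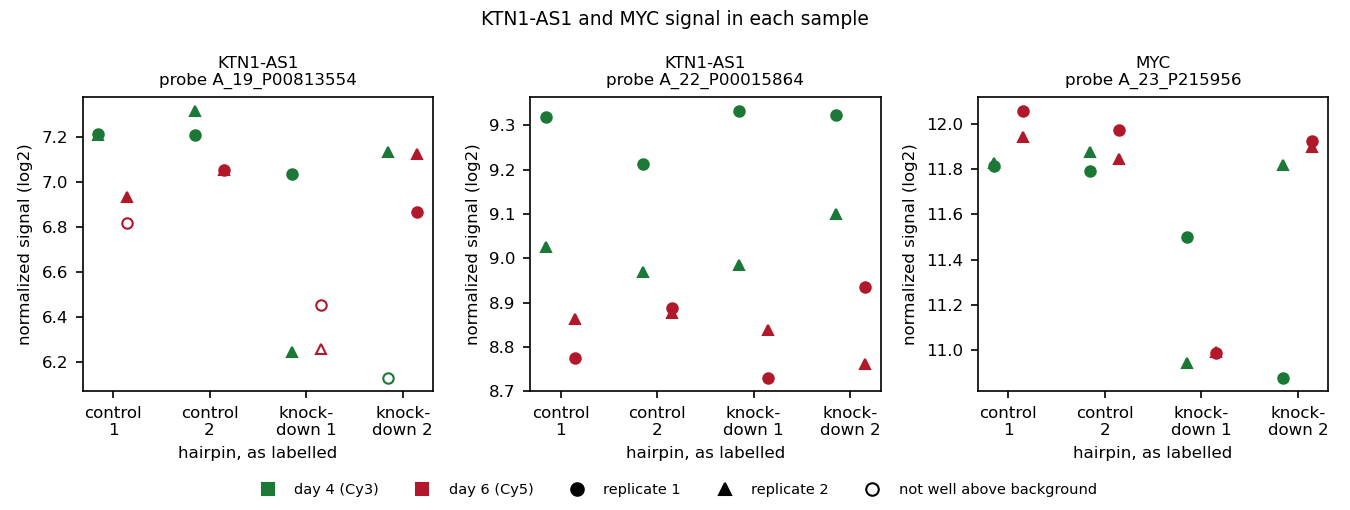
Normalized log2 signal of both KTN1-AS1 probes and of MYC in each of the 16 samples, by hairpin as labelled, with colour for day and dye, shape for replicate and hollow points for spots not well above background. MYC lay between 11.79 and 12.06 in the control samples. It lay near 10.99 in both day 6 samples labelled hairpin 1, and at 11.92 and 11.90 in those labelled hairpin 2.

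The first comparison asked which genes changed in the knockdown arm, both hairpins pooled, over the mean of both days. The largest named rises were in 4 long noncoding RNAs: NALF1-IT1 was 5.12-fold higher (log2 2.36 ± 0.27 SE, adjusted p = 0.00193), CASC15 4.14-fold, LINC02245 4.02-fold and CCNT2-AS1 3.57-fold (each n = 4 arrays against 4). RNU6ATAC, a small nuclear RNA of the minor spliceosome, rose 3.11-fold (log2 1.64 ± 0.17). Among protein-coding genes, the phosphatase gene DUSP26 rose 2.87-fold (log2 1.52 ± 0.13), CD86, a costimulatory ligand on B cells, 2.74-fold (1.45 ± 0.23), the kinase gene CDK16 2.47-fold (1.31 ± 0.12) and PTCRA, the pre-T cell receptor alpha chain, 2.47-fold (1.30 ± 0.12). DNAJB2, a co-chaperone gene, rose 2.49-fold on its brightest probe, and the difference on its second probe was 0.17 (adjusted p = 0.41).

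The falls were smaller. MARCKSL1, an actin-binding protein gene, fell 2.24-fold (log2 −1.16 ± 0.20, adjusted p = 0.0111), and CBFB, the partner of RUNX transcription factors, 2.13-fold (−1.09 ± 0.25, adjusted p = 0.033). TFRC, the transferrin receptor that brings iron into cells, fell 1.86-fold (−0.90 ± 0.08), LTB, the cytokine lymphotoxin beta, 1.97-fold (−0.98 ± 0.16), and BCL11A, a transcription factor of B cell development, 1.89-fold (−0.92 ± 0.20). The other BCL11A probes fell less than this brightest one (−0.47, −0.21 and −0.27). The others among the 10 named falls were SNORA67 (−0.99), WNK2 (−0.96, and −0.20 on a second probe), EI24 (−0.91), AASDHPPT (−0.90) and CHI3L2 (−0.86). In all 20 named genes, every one of the 4 knockdown arrays lay beyond every control array, which their choice by size and shared direction favours. Their size was not always shared: at day 6, 17 of the 20 passed with both hairpins, and not SNORA67 (−0.62 with hairpin 2), AASDHPPT (−0.47 with hairpin 2) and LTB (−0.41 with hairpin 1). The hairpins differed at day 6 in 7 of the 20, CBFB (−1.39), DNAJB2 (1.19), BCL11A (−1.05), SNORA67 (−0.90), NALF1-IT1 (−0.89), LTB (0.88) and PTCRA (0.62). In total 2004 of 26762 features changed, 1136 higher and 868 lower, and 28 of them by more than 2-fold.

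Lists of growth and biosynthesis genes were among the 9 of 35 gene lists that passed camera as lower, although many members of each did not pass singly and no list passed with an estimated correlation. Of 60 MYC-induced nucleolar and growth genes, 20 fell and none rose (33 adjusted over the list alone), with a median of −0.26 (adjusted p = 3.2e-15 by camera, adjusted p = 0.0574 with an estimated correlation). They included PA2G4 (−0.64 ± 0.07), the pseudouridine synthase gene DKC1 (−0.49 ± 0.06), the replicative helicase gene MCM4 (−0.60 ± 0.08) and the folate carrier gene SLC19A1 (−0.54 ± 0.08). Of 24 genes of sterol synthesis and uptake, 12 fell (13 adjusted over the list alone), with a median of −0.31 (adjusted p = 9.1e-11, adjusted p = 0.0514 with an estimated correlation). Among them were DHCR7 (−0.76 ± 0.08), HMGCS1 (−0.75 ± 0.10), MSMO1 (−0.58 ± 0.07) and FDPS (−0.44 ± 0.06). Of 38 translation factors and aminoacyl-tRNA synthetases, 11 fell (15 adjusted over the list alone), such as WARS1 (−0.73 ± 0.15), EIF1AX (−0.52 ± 0.10), EIF4A1 (−0.45 ± 0.08) and EIF3J (−0.42 ± 0.07, and 0.03 on a second probe). Their median was −0.18 (adjusted p = 2.8e-08, adjusted p = 0.0574 with an estimated correlation). Of 21 glycolysis genes, 4 fell, GPI (−0.51), ALDOC (−0.39), TPI1 (−0.29) and HK1 (−0.18), and 11 did adjusted over the list alone. Their median was −0.21 (adjusted p = 2.3e-07, adjusted p = 0.0574 with an estimated correlation). Of 27 nucleotide synthesis genes, 6 fell (8 adjusted over the list alone), including PRPS2 (−0.54), UMPS (−0.49), MTHFD1 (−0.43) and DUT (−0.28). Their median was −0.28 (adjusted p = 4.0e-07, adjusted p = 0.0693 with an estimated correlation). Of the 60 MYC-induced genes, 8 also stood in another list.

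A further 4 lists fell. Of 44 genes of DNA replication and S phase, 10 fell, with MCM4, GINS2 (−0.58), MCM6 (−0.45) and POLA1 (−0.38) among them (2 higher and 15 lower adjusted over the list alone). The median was −0.14 (adjusted p = 6.1e-06, adjusted p = 0.0842 with an estimated correlation). Of 24 genes of the unfolded protein response of the endoplasmic reticulum, 5 fell, including the chaperone and folding genes PDIA4 (−0.66), MANF (−0.47), CALR (−0.44) and HYOU1 (−0.42) (9 adjusted over the list alone). The median was −0.20 (adjusted p = 6.1e-05, adjusted p = 0.0514 with an estimated correlation). Of 25 cytosolic chaperones, 6 fell, including HSP90AB1 (−0.64), FKBP4 (−0.63), CHORDC1 (−0.38) and HSPD1 (−0.27) (7 adjusted over the list alone). The median was −0.12 (adjusted p = 1.4e-04, adjusted p = 0.0693 with an estimated correlation). Of 43 splicing factors, 5 fell and 1 rose, with HNRNPM (−0.37), HNRNPA3 (−0.34), HNRNPD (−0.27) and SNRPD3 (−0.26) among the falls (7 and 1 adjusted over the list alone). The median was −0.12 (adjusted p = 0.00513, adjusted p = 0.0686 with an estimated correlation).

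The lists that rose were 4. Of 36 interferon-stimulated genes, 9 rose and none fell (19 adjusted over the list alone), among them STAT2 (0.99 ± 0.12), IFIH1 (0.47 ± 0.05), IRF1 (0.35 ± 0.08) and OAS1 (0.33 ± 0.07). Their median was 0.23 (adjusted p = 5.0e-08, adjusted p = 0.0574 with an estimated correlation). Of 32 genes of lysosome and autophagy, 7 rose and 1 fell (12 and 2 adjusted over the list alone). The median was 0.16 (adjusted p = 3.0e-04, adjusted p = 0.0574 with an estimated correlation). The autophagy receptor SQSTM1 rose by 0.61, CTSA by 0.42 and LAMP1 by 0.24, and ATG7 was −0.25 on its brightest probe and passed the other way on a second. Of 21 MYC-repressed genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone). The median was 0.18 (adjusted p = 9.7e-04, adjusted p = 0.0574 with an estimated correlation). BTG2, an antiproliferative gene, rose by 1.06 ± 0.12, TXNIP, an inhibitor of glucose uptake, by 1.05 ± 0.05, and KLF6 by 0.51 ± 0.06 (0.12 on a second probe, not past), whereas GADD45A fell by 0.37. Of 27 immediate early genes, 3 rose, BTG2, KLF6 and ZFP36 (0.36) (5 higher and 1 lower adjusted over the list alone), and IER2 was 0.37 higher without passing. Their median was 0.16 (adjusted p = 0.00608, adjusted p = 0.0574 with an estimated correlation). BTG2 and KLF6 stand in both of the last lists, so these are not separate evidence.

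The other 22 lists did not pass, with medians from −0.08 to 0.13. In B cell identity, none of 8 B cell markers changed (2 higher adjusted over the list alone, median 0.03, adjusted p = 0.542), with MS4A1 at 0.36. Of 29 B cell receptor signalling genes, 2 rose, CD72 (0.42) and INPP5D (0.28) (2 higher and 1 lower adjusted over the list alone). The median was −0.0049 and mean 0.0025 (adjusted p = 0.981). Of 31 germinal centre genes, 2 rose, IRAG2 (0.60) and TCF3 (0.52) (4 and 1 adjusted over the list alone). The median was 0.07 (adjusted p = 0.26). Of 23 plasma cell genes 3 fell, FKBP11 (−0.71) and SSR4 (−0.42) among them (3 adjusted over the list alone). The median was −0.08 (adjusted p = 0.264). HLA class I had 2 rises and 1 fall among 19 genes (3 and 1 adjusted over the list alone), with NLRC5 at 0.21 and CALR at −0.44. Their median was −0.05 (adjusted p = 0.689). HLA class II had 1 rise among 19, IFI30 (0.52), with HLA-DOB at −0.49 and not past (1 adjusted over the list alone). The median was −0.06 (adjusted p = 0.542). NF-kB targets had 2 rises, CCL3 (0.87) among them, and 1 fall, NFKB1 (−0.53), among 22 genes (3 and 2 adjusted over the list alone). The median was 0.00 (adjusted p = 0.581). Of 26 p53 targets, 2 rose, BTG2 and TP53INP1 (0.57), and 1 fell (5 and 1 adjusted over the list alone). The median was −0.03 and mean 0.06 (adjusted p = 0.503). Of 31 apoptosis regulators 3 rose, with BIRC2 at 0.35 and BMF at 0.33, and 1 fell (3 and 1 adjusted over the list alone). The median was 0.03 (adjusted p = 0.453). In the MYC network, MXD3 (0.51) and MLXIP (0.43) rose on their brightest probes but not on second probes (0.10 and −0.09), and 1 of 21 genes fell (3 and 2 adjusted over the list alone). The median was 0.00 (adjusted p = 0.733).

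Among 46 genes of G2/M and mitosis, PRC1 (0.41) and CDC25B (0.40) were among 3 that rose, and 1 fell (3 and 2 adjusted over the list alone). The median was 0.01 (adjusted p = 0.981). Among 16 histone genes H1-5 (0.31) rose, and H1-2 was at 0.28 (1 adjusted over the list alone). The median was 0.08 (adjusted p = 0.232). Among 72 cytosolic ribosomal protein genes, RPS4X (0.20) rose and RPL28 (−0.25) fell on its brightest probe and passed the other way on a second (none adjusted over the list alone). Their median was 0.00 (adjusted p = 0.733). With signals scaled to the 75th percentile the median was −0.12 and the list passed camera (adjusted p = 7.5e-04). Mitochondrial respiratory chain genes had 3 rises and 3 falls, UQCRC2 (−0.53) among the falls, of 38 (4 and 6 adjusted over the list alone). The median was −0.07 (adjusted p = 0.287). Proteasome genes had 1 fall of 31, PSMD12 (−0.37), with PSMA5 at −0.23 (2 higher and 4 lower adjusted over the list alone). The median was −0.05 (adjusted p = 0.261). Of 25 ATF4 response genes, 2 fell, PSAT1 (−0.63) and SLC38A2 (−0.42), and 1 rose (2 and 1 adjusted over the list alone). The median was −0.06 (adjusted p = 0.26). Of 17 hypoxia genes 1 fell, BNIP3 (−0.33), with PFKFB3 also at −0.33 and not past (1 adjusted over the list alone). The median was −0.06 (adjusted p = 0.531). The RNA interference machinery had 1 rise of 13, TNRC6B (0.27), with TARBP2 at 0.22 (3 higher and 1 lower adjusted over the list alone). The median was 0.03 (adjusted p = 0.581). Of 17 neighbours of KTN1-AS1 on chromosome 14, 2 fell, GCH1 (−0.57) and EXOC5 (−0.23) (2 adjusted over the list alone). The median was 0.02 and mean −0.03 (adjusted p = 0.812). Markers of other cell types gave no change in 7 T cell genes (CD3D −0.07, CD3E 0.03, median 0.00, adjusted p = 0.981) or in 3 myeloid genes (CD14 0.13, ITGAM 0.15, median 0.13, adjusted p = 0.581). Of 5 fibroblast or epithelial genes VIM (0.45) rose, with KRT19 at 0.02 (1 adjusted over the list alone). The median was 0.02 (adjusted p = 0.503).

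Camera passed 13 of the 35 lists with the preset correlation, 4 up and 9 down, 0 with an estimated correlation, and fry passed 15. With replicate number as a block 3082 features changed. Agilent's processed signals gave 611 (quantiles) and 632 (75th percentile), the authors' table gave 617, and leaving out any 1 of the 4 control arrays gave 737 to 1103. Of 36 named genes with several probes, 15 passed on the brightest probe and not on another, CHORDC1, CTSA, DNAJB2, DUT, EIF1AX, EIF3J, GCH1, HNRNPA3, HNRNPD, KLF6, MLXIP, MXD3, NLRC5, RPL28 and SLC38A2. CBFB, SNORA67 and BCL11A did not pass with the processed signals or the authors' table, and MARCKSL1 did not with processed signals scaled by quantiles.

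**Figure D2:**
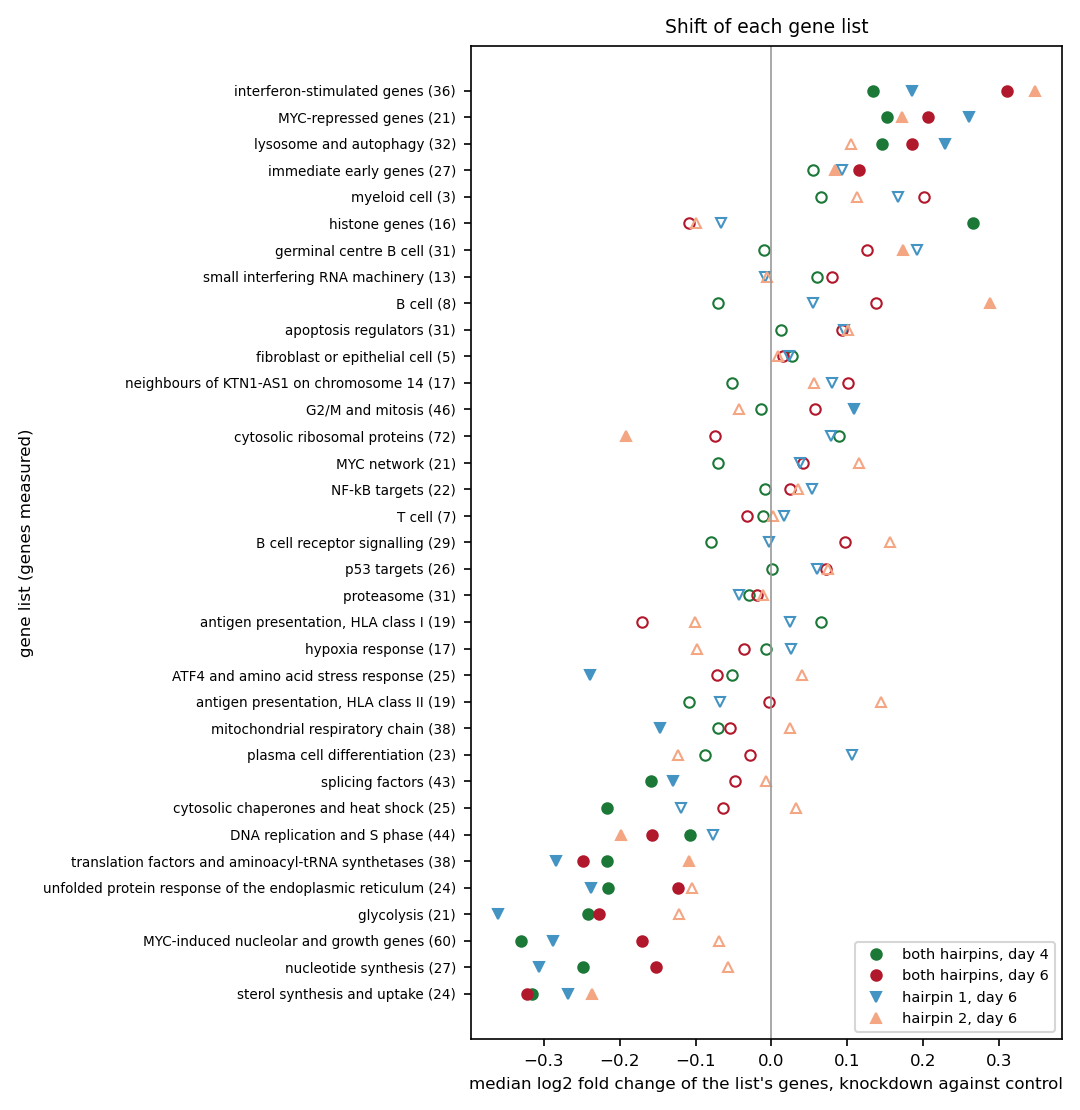
Median log2 fold change of the measured members of each of the 35 gene lists (number in brackets), for both hairpins at day 4 and day 6 and for each hairpin at day 6. Filled points passed camera with the preset correlation. Interferon-stimulated genes lie at the top with a median of 0.31 at day 6 and sterol genes at the bottom with a median of −0.32.

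At day 4, NALF1-IT1 (3.50-fold), RNU6ATAC (2.94-fold) and LINC02245 (2.90-fold) were the largest named rises, and EI24 (2.25-fold), TFRC (2.16-fold) and LTB (2.15-fold) the largest named falls. At day 6 the rises were NALF1-IT1 (7.50-fold), CASC15 (6.16-fold) and LINC02245 (5.57-fold), and the falls CHI3L2 (2.25-fold), COL18A1, a basement membrane collagen (2.21-fold), and MARCKSL1 (2.21-fold). Adjusted p ranged from 0.00741 to 0.0392 for the genes of day 4 and from 5.8e-04 to 0.00706 for those of day 6 (n = 4 arrays against 4). The median of MYC-induced genes was −0.33 at day 4 (9 fell, 40 adjusted over the list alone, adjusted p = 5.2e-25, adjusted p = 0.0228 with an estimated correlation) and −0.17 at day 6 (6 fell, 19 lower and 2 higher adjusted over the list alone, adjusted p = 3.3e-05, adjusted p = 0.333 with an estimated correlation). Sterol genes had medians of −0.32 on both days (7 and 8 fell, 14 and 12 adjusted over the list alone, adjusted p = 8.3e-12 and 4.8e-07, adjusted p = 0.0258 and 0.0283 with an estimated correlation). Interferon-stimulated genes had medians of 0.13 at day 4 and 0.31 at day 6 (1 and 9 rose, 1 higher, then 18 higher and 1 lower, adjusted over the list alone, adjusted p = 8.8e-06 and 4.8e-07, adjusted p = 0.11 and 0.0676 with an estimated correlation). Camera passed 13 lists at day 4, of which 5 passed with an estimated correlation (MYC-induced genes, sterol genes, the unfolded protein response, splicing factors, and lysosome and autophagy), and 11 at day 6, of which only sterol genes did.

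At day 4, 480 features changed, 204 higher and 276 lower, and at day 6 1641, 1027 higher and 614 lower. Of these, 124 rose and 106 fell on both days and none went opposite ways. Both days came from the same arrays, so these are not independent lists. All day 4 samples were in Cy3 and all day 6 samples in Cy5, so the counts cannot tell day from dye. With replicate number as a block the counts were 1592 at day 4 and 1531 at day 6. With hairpin as a fixed term, limma called 0 at day 4 (3281 at unadjusted p under 0.05) and 4374 at day 6, and with hairpin as a random block 3830 and 823. The correlation within hairpins in the block fit was −0.47 at day 4 and 0.20 at day 6. A negative correlation narrows the error of the arm difference, so 3830 is no sign of a stronger effect. With hairpin as a fixed term the error holds only the spread between replicates of a hairpin. Differences between hairpins are left out of that error, so 4374 does not speak for hairpins beyond these. Agilent's processed signals and the authors' table gave 68 to 125 at day 4 and 189 to 192 at day 6. The larger number of falls at day 4 (42.5% of the called features higher) turned into more rises under other scalings: 64.0% and 52.9% were higher with processed signals (quantiles and 75th percentile), 67.3% in the authors' table and 52.9% with quantile normalization without loess. Leaving out 1 control array gave 17 to 24 at day 4 and 449 to 1493 at day 6. Without the knockdown samples of replicate 1, whose hairpin difference at day 4 ran opposite to that of the other samples, 3210 changed at day 4. That fit sets knockdown samples of replicate 2 alone against controls of both replicates, so arm and replicate are partly joined in it. The split of all arrays by replicate number gave 643 at day 4. An exchange of hairpin numbers within the arm would leave the pooled count of 480 as it is.

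The knockdown effect differed between day 4 and day 6 in 38 features, 24 with a higher and 14 with a lower value at day 6. A dye effect that depends on signal level would not cancel between arms, so these differences may be of day or of dye. The rise was larger at day 6 for CASC15 (difference 1.14 ± 0.11 log2 units, adjusted p = 0.00825), NALF1-IT1 (1.097 ± 0.14, adjusted p = 0.0206) and CCNT2-AS1 (1.03 ± 0.11, adjusted p = 0.00825). Replication-dependent histone genes moved the other way: H2AC15 was at 0.21 at day 4 and −0.71 at day 6 (difference −0.92 ± 0.12), H2AC11 at 0.39 and −0.52 (−0.91 ± 0.11) and H3C15 at 0.13 and −0.75 (−0.88 ± 0.11). Across 16 histone genes the day difference had a median of −0.40, and 2 were lower (7 adjusted over the list alone; adjusted p = 3.0e-08, adjusted p = 0.407 with an estimated correlation). MYC-induced genes (median 0.17, adjusted p = 0.00687, adjusted p = 0.619 with an estimated correlation), cytosolic chaperones (median 0.11, adjusted p = 0.0306, adjusted p = 0.49 with an estimated correlation) and B cell markers (median 0.37, adjusted p = 0.0408, adjusted p = 0.49 with an estimated correlation) were relatively higher at day 6, with no single member past the test over all genes. With Agilent's processed signals and the authors' values, 0 features passed in limma (2071 to 2157 at unadjusted p under 0.05), and without both knockdown arrays of replicate 1, 739 did. The latter fit sets knockdown arrays of replicate 2 alone against controls of both replicates. Leaving out any array moved the count to between 0 (without knockdown hairpin 1 replicate 2) and 170 (without knockdown hairpin 2 replicate 1), and with replicate number as a block it was 41. With hairpin as a fixed term it was 15.

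Each knockdown hairpin was then set against both controls. Over the mean of both days, 876 features changed with hairpin 1 (505 higher, 371 lower) and 398 with hairpin 2 (207 higher, 191 lower), of which 165 rose and 118 fell with both and none went opposite ways, in comparisons that share their 4 control arrays. MYC-induced genes had a median of −0.29 with hairpin 1 (14 fell, 34 adjusted over the list alone, adjusted p = 1.5e-17, adjusted p = 0.0926 with an estimated correlation) and −0.21 with hairpin 2 (4 fell, 15 adjusted over the list alone, adjusted p = 4.1e-11, adjusted p = 0.13 with an estimated correlation). Interferon-stimulated genes had medians of 0.16 and 0.21 (4 and 2 rose, 9 and 10 adjusted over the list alone, adjusted p = 1.0e-05 and 4.1e-09, adjusted p = 0.223 and 0.13 with an estimated correlation). These values include the day 4 samples of replicate 1, each of which carried the profile of the other hairpin, as described below. The one labelled hairpin 2 correlated with the day 6 profile of hairpin 1 (r = 0.552). The fall of MYC-induced genes therefore cannot be credited to hairpin 2 alone. With 2 arrays per hairpin the counts were unsteady: with replicate number as a block they were 2253 and 1331, with processed signals and the authors' values 32 to 43 (26 to 30 higher, 6 to 13 lower) and 17 to 30 (16 to 28 higher, 1 to 2 lower), and without 1 control array 0 to 6 and 0.

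The hairpin effects correlated across genes with r = 0.758 when both were taken against all controls, where simulated unchanged groups gave 0.329 from the shared controls alone, and with r = 0.636 and 0.586 when each hairpin was set against a different control. Genes are not independent replicates, so no p is given. Without 1 array, r ranged from 0.584 to 0.774. With processed signals or the authors' table it was 0.635 to 0.660, and at day 6 alone 0.550 (simulated 0.334, and 0.417 and 0.368 with separate controls). The mean of both days includes the day 4 samples of replicate 1, each of which carried the profile of the other hairpin, as described below. That mixing may raise r and keep changes in opposite directions from being called.

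Between the knockdown hairpins, 0 features differed over the mean of both days in limma, with 1208 at an unadjusted p under 0.05, and the smallest p belonged to RFTN1 (0.79 ± 0.09), BBIP1 (0.64 ± 0.10) and MICB (0.54 ± 0.09), none past the test. At day 6 alone, a comparison added after the data were seen, 1700 differed, 766 higher and 934 lower with hairpin 1. MYBPC2, a myosin-binding protein gene, was 2.78 log2 units above controls with hairpin 1 and −0.07 with hairpin 2 (difference 2.85 ± 0.17, adjusted p = 7.6e-05), and SCARNA13, a small Cajal body RNA, was at −0.36 and 2.24 (difference −2.61 ± 0.15, adjusted p = 7.6e-05). RPIA (1.76), ZFHX3 (1.65), LIMS2 (1.62) and STAG3 (1.48) were the next higher with hairpin 1, and KIF19 (−1.93), SCML4 (−1.91), VMA21 (−1.89) and MYLK3 (−1.82) the next lower. Against controls at day 6, 3885 features changed with hairpin 1 and 2678 with hairpin 2, of which 756 rose and 435 fell with both and 72 went opposite ways.

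At day 6 MYC-induced genes were lower with hairpin 1 than with hairpin 2 (median difference −0.17, 6 lower, 17 lower and 1 higher adjusted over the list alone, adjusted p = 2.4e-06, adjusted p = 0.232 with an estimated correlation), as were nucleotide synthesis (−0.16, 7 lower and 1 higher, adjusted p = 2.7e-04, adjusted p = 0.21 with an estimated correlation), glycolysis (−0.14, 3 lower, adjusted p = 2.7e-04, adjusted p = 0.302 with an estimated correlation) and HLA class II genes (−0.28, 4 lower and 1 higher, adjusted p = 3.3e-04, adjusted p = 0.21 with an estimated correlation). Translation factors (−0.15), respiratory chain genes (−0.18) and ATF4 response genes (−0.18) were also lower (adjusted p = 0.0011 to 0.0037, adjusted p = 0.21 to 0.365 with an estimated correlation). Cytosolic ribosomal proteins (0.33, 2 higher), G2/M genes (0.19, 8 higher) and DNA replication genes (0.13, 4 higher and 3 lower) were higher with hairpin 1 (adjusted p = 5.9e-07, 2.1e-05 and 0.0318, adjusted p = 0.579, 0.435 and 0.485 with an estimated correlation). Against controls at day 6, 13 lists passed with hairpin 1 and 9 with hairpin 2, none with an estimated correlation.

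**Figure D3:**
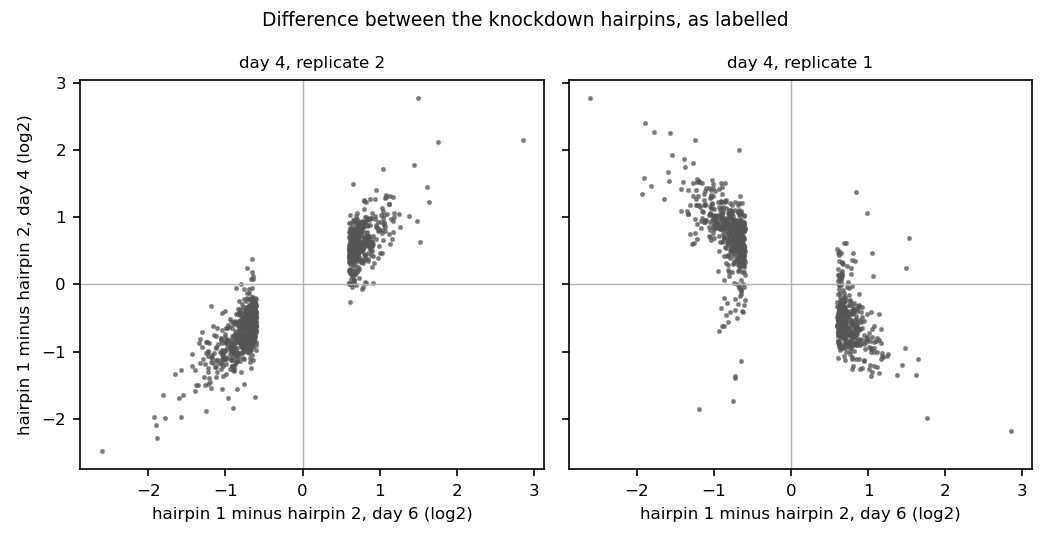
Difference between the knockdown hairpins (hairpin 1 minus hairpin 2, log2) at day 6, averaged over replicates, against the day 4 difference in replicate 2 (left) and replicate 1 (right). Points are the 900 genes with the largest day 6 difference. The day 4 difference had the sign of day 6 in 887 of the 900 genes in replicate 2 and the opposite sign in 833 in replicate 1.

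The difference between the knockdown hairpins in the day 4 samples of replicate 1 ran against that in all other pairs. Across all genes it correlated with r = −0.65 with day 4 replicate 2 and −0.53 and −0.60 with the day 6 replicates, whereas those 3 pairs correlated with each other with r from 0.618 to 0.746. The control hairpins gave r from 0.150 to 0.316 in every combination. MYC followed this pattern, at 11.50 and 10.94 in the day 4 samples labelled hairpin 1 and at 10.88 and 11.82 in those labelled hairpin 2 (replicates 1 and 2). Comparisons that join day 4 samples of a hairpin therefore mix unlike samples. On a single day the knockdown arm holds the same 4 samples whichever hairpin numbers are right. The mean of both days and the day difference join both days of each array. There the arm means would stay the same, but the spread between knockdown arrays, and so the counts, could differ.

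The control hairpins served as background, and 0 features differed between them over the mean of both days in limma (1198 at an unadjusted p under 0.05) or at day 6 (3365). The smallest p belonged to RN7SL1 (−0.88 ± 0.10), KCNH3 (0.54 ± 0.09) and DYNLRB1 (−0.71 ± 0.13), none past the test. Without control hairpin 2 replicate 1, 7 features differed.

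Between day 6 and day 4 in control cells, 6143 features differed, 2516 higher and 3627 lower at day 6, a contrast that joins day with dye. RPS27 (2.04 ± 0.33), the small GTPase gene RIT1 (2.02 ± 0.31) and RPL13 (1.99 ± 0.33) were highest at day 6, and the actin-binding cofilin CFL1 (−1.31 ± 0.17), VAC14 (−1.30 ± 0.18) and NT5DC2 (−1.24 ± 0.15) lowest (adjusted p = 8.7e-04 to 0.003). RPS27 was at −0.03 with Agilent's processed signals scaled by quantiles and in the authors' table. Without control hairpin 1 replicate 1 the count was 2975, without control hairpin 2 replicate 1 it was 3972, and with replicate number as a block it was 6788.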

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

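The tests of exchanged samples, of a slower response, of a shared sequence, of whole transcripts, of an effect of both hairpins on MYC and of the depth of depletion were chosen only after the results they bear on had been seen.

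The difference between the knockdown hairpins in the day 4 samples of replicate 1 ran opposite to that of the other 3 pairs of samples (r = −0.668 across genes with their mean), where the control hairpins gave r = 0.345. The tables argue against normalization, since r was −0.421 with Agilent's processed signals scaled to the 75th percentile and no more than −0.412 with any of the 5 normalizations. They also argue against a slower response to hairpin 1 in that replicate: the day 4 sample labelled hairpin 2 carried the day 6 hairpin profile in the direction of hairpin 1 (r = 0.552), and the one labelled hairpin 1 did not (r = −0.136). An exchange of these 2 samples stays open and may account for the pattern, because across genes each of them carried the profile of the other hairpin, but 67 of the 900 genes with the largest day 6 difference kept the labelled direction, NALF1-IT1 (−0.62), CASC15 (−0.61), CD86 (−0.41) and LINC02245 (−0.38) among them. At which step samples could have been exchanged, and which pair carries the right hairpin numbers, cannot be read from the data, so the labels were kept.

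Among the largest rises, 4 long noncoding RNAs (NALF1-IT1, CASC15, LINC02245 and CCNT2-AS1) followed each other across the 16 samples, with r from 0.931 to 0.985 over 6 pairs after the mean of each arm on each day was taken off, and from 0.270 to 0.803 in the 8 control samples. Over the 8 arrays, which may hold technical replicates, r was 0.959 to 0.992 (exact permutation p = 2.98e-04 to 0.00546, adjusted p = 0.00179 to 0.00546) and rho 0.690 to 0.952 (exact permutation p = 0.00114 to 0.0694, adjusted p = 0.00342 to 0.0694), but without the 2 arrays farthest from the median r was 0.262 to 0.891, so the relation rests largely on those arrays. The permutations moved arrays across arms after the arm means were taken off. Arrays of the arms may differ in spread, so these permutation p values are approximate. Background handling is argued against. Over the mean of both days the smallest of the 4 rises (CCNT2-AS1, 1.84 log2 units) was 2.26 with Agilent's processed signals scaled to the 75th percentile. Probes that read 1 shared sequence stay open as a candidate explanation, but of 20 other features with a larger effect at day 6, 9 had r above 0.9 with the mean of the 4, CD86 (0.958) among them, and transcripts regulated together could do the same. A rise of the whole transcript cannot be told apart from this: second probes of CASC15 and CCNT2-AS1 changed by 0.0523 and −0.0729 at day 6, but were well above background in only 1 and 2 of 16 channels.

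MYC was lower at day 6 with hairpin 1 and not detectably with hairpin 2. Normalization is argued against, as the hairpins differed by −0.98 (adjusted p = 0.0404 in limma) with processed signals scaled to the 75th percentile. At day 6, an effect of both hairpins on MYC of 0.5 log2 units or more is argued against by the lower 95% bound of −0.23 with hairpin 2. That bound rests on 2 arrays with hairpin 2, which may be technical replicates, and does not cover day 4. At day 4, both knockdown samples of replicate 1 (11.50 labelled hairpin 1, 10.88 labelled hairpin 2) lay below the lowest control (11.79). In replicate 2, hairpin 1 was at 10.94 and hairpin 2 at 11.82. Whether the fall of −0.97 with hairpin 1 may follow from a deeper loss of KTN1-AS1, whose dimmer probe read lower in the same samples, not well above background, while its brighter probe differed by −0.066 ± 0.089 (adjusted p = 0.718 in limma), or from other targets of hairpin 1, cannot be told apart, since each hairpin has 1 sequence and 1 depth of depletion.

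The knockdown effect differed between day 4 (Cy3) and day 6 (Cy5) in 38 features. A dye effect that depends on signal level cannot be told from day in them. Day 6 minus day 4 was 1.097 for NALF1-IT1, 1.145 for CASC15, 0.9431 for LINC02245, 1.032 for CCNT2-AS1 and 0.9178 for CD86, and it was −0.924 for H2AC15, −0.9102 for H2AC11 and −0.8767 for H3C15. Of the gene lists, the day difference passed camera for histone genes (adjusted p = 3.033e-08), MYC-induced genes (0.006868), cytosolic chaperones (0.03057) and B cell markers (0.04075), and for 0 lists with an estimated correlation or by fry.

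In 12 of 308 groups of 4 arrays, 1 array stood apart by a gap to its nearest neighbour, as a share of the group's range, above Dixon's 95% critical value, and chance alone gives about 1 in 20. Knockdown hairpin 2 replicate 2 was lowest for KTN1 (0.9101) and GINS2 (0.869) and highest for IRAG2 (0.9727), and knockdown hairpin 1 replicate 2 was highest for UQCRC2 (0.897) and lowest for MTHFD1 (0.9326) and FKBP11 (0.8355). Control hairpin 1 replicate 1 was lowest for PRC1 (0.8552), HNRNPA3 (0.859) and the day ratios of CCNT2-AS1 (0.8404) and H2AC11 (0.8692), and highest for EXOC5 (0.9099), and control hairpin 2 replicate 2 was lowest for DUT (0.9146).

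The 8 arrays can be split into 4 and 4 in 35 ways. For the mean of both days (2004 features), for day 6 (1641) and for the day difference (38), the real split was the only 1 to reach its count and the highest other gave 0. For day 4, 2 of 35 splits reached 480, so chance cannot be excluded. The other was the split by replicate number, which is also the slide row, with 643, and with replicate number as a block 1592 features changed. The replicate numbers pair the arrays, and 18 splits have as many arrays of each replicate on both sides. Of these the highest other gave 0 for all 4 counts, but 18 are too few for a share under 0.05. The hairpin is the treated unit, and only a few of the 35 splits keep both arrays of every hairpin together. The highest other of those also gave 0 for all 4 counts, but they are too few for such a share. Chance between hairpins therefore cannot be excluded for any of the 4 counts. The arms also lay in different slide columns, which no split can tell from the hairpins. For the counts of gene lists chance cannot be excluded: 4 splits reached the 13 lists of the mean of both days (highest other 14), 6 the 13 of day 4 (16) and 6 the 11 of day 6 (14).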

How the results depend on the processing

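Day 6 samples alone and leaving out both knockdown arrays of replicate 1 were tried only after the results were seen, and the other alternatives were planned. KTN1-AS1 (brighter probe) stayed within −0.03 to 0.04 without any 1 array and did not pass under any alternative tried for it. The gene list counts of the mean of both days were 12 to 17 under the alternatives tried for them, apart from the estimated correlation (12 without both knockdown arrays of replicate 1). Neither was refitted with hairpin as a random block or fixed term, or with all 16 samples in 1 fit. Of the features called on the mean of both days, 1999 of 2004 kept their sign and 522 stayed past the threshold with processed signals scaled by quantiles, and 1824 did with quantile normalization without loess. Results of genes chosen by the naming rule that lost their call numbered 61 with processed signals scaled by quantiles, 58 with the 75th percentile and 61 with the authors' table, of 144 such results. The cause was not tested for the changes that follow. Leaving out an array leaves fewer samples, but counts also rose without some knockdown arrays, which fewer samples alone do not account for. A random hairpin block changes the error through its correlation. A fixed hairpin term leaves differences between hairpins out of the error. On the mean of both days, processed signals gave 611 (quantiles) and 632 (75th percentile) features, the authors' values 617 and the replicate block 3082. On day 4 these gave 125, 68, 110 and 1592, hairpin as a random block 3830 and as a fixed term 0 (3281 at unadjusted p under 0.05). The 3830 goes with a correlation within hairpins of −0.47, which narrows the error of the arm difference. On day 6, processed signals gave 189 and 192, the authors' values 192, hairpin as a random block 823 and as a fixed term 4374. For the day difference, processed signals and the authors' table gave 0 (2071 to 2157 unadjusted), quantile normalization without loess 25, the stricter filter 22 and hairpin as a fixed term 15. For hairpin 1, processed signals gave 32 and 43, the authors' values 32, the replicate block 2253 and day 6 samples 3885. For hairpin 2 they gave 30, 20, 17, 1331 and 2678, and between the knockdown hairpins day 6 samples gave 1700. The share of called features that were higher was 56.7% on the mean of both days, 67.6% with processed signals scaled by quantiles and 66.6% in the authors' table. The correlation of the hairpin effects was 0.660, 0.635 and 0.658 with the processed signals and the authors' table, and 0.550 in day 6 samples. With an estimated correlation 0 lists passed on the mean of both days, 5 on day 4 and 1 on day 6.

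Leaving out 1 array, the count ran from 737 to 2546 on the mean of both days (917, 979, 737 and 1103 without control hairpin 1 replicate 1, hairpin 2 replicate 1, hairpin 1 replicate 2 and hairpin 2 replicate 2), from 17 to 901 on day 4 (24, 18, 22 and 17 without those, 901 and 116 without knockdown hairpin 1 replicates 1 and 2, and 248 without hairpin 2 replicate 2) and from 449 to 1493 on day 6 (617, 449 and 1027 without control hairpin 1 replicates 1 and 2 and hairpin 2 replicate 2, and 745 without knockdown hairpin 1 replicate 2). Without both knockdown arrays of replicate 1 the counts were 2846 and 3210 on the mean of both days and day 4. That setting leaves knockdown arrays of replicate 2 alone against controls of both replicates, so arm and replicate are partly joined. The day difference ran from 0 to 170 (13, 14, 9 and 10 without the controls in the order above, 123 and 0 without knockdown hairpin 1 replicates 1 and 2, and 170 and 14 without hairpin 2 replicates 1 and 2), and was 739 without both knockdown arrays of replicate 1. For hairpin 1 it ran from 0 to 1865 (5, 6, 5 and 0 without the controls, 1865 and 39 without its own replicates, and 1724 without either replicate of hairpin 2), and for hairpin 2 from 0 to 1015 (0 without any control, with 3003 to 3628 unadjusted, 705 without either replicate of hairpin 1, and 1015 and 129 without its own). In these fits the lone array of a hairpin is assumed to vary like the others. The knockdown hairpins differed in 0 to 20 (20 without hairpin 2 replicate 1), the control hairpins in 0 to 7 (7 without hairpin 2 replicate 1), and day 6 from day 4 in 2975 to 7480 (2975 and 3972 without replicate 1 of control hairpins 1 and 2). List counts ran from 13 to 13, 13 to 17 and 10 to 14, and the correlation of the hairpins from 0.584 to 0.774. Signs turned for RPL28 (0.0941 as the mean of its probes), RPS4X (−0.0967 with the 75th percentile), RPS27 between days (−0.0316 with quantiles and −0.0317 in the authors' values) and the median of ribosomal proteins, which was −0.125 on the mean of both days and −0.121 on day 4 with the 75th percentile. Without 1 array that median ran from −0.0918 (without knockdown hairpin 2 replicate 1) to 0.169 on day 4 and from −0.131 to 0.11 (without knockdown hairpin 2 replicate 1) on day 6, and it was −0.147 on day 4 without both knockdown arrays of replicate 1. In these turned settings the ribosomal list passed camera. With the 75th percentile, adjusted p was 7.5e-04 on the mean of both days and 0.0248 on day 4. Without knockdown hairpin 2 replicate 1 it was 0.00239 on day 4 and 0.0233 on day 6, and without both knockdown arrays of replicate 1 it was 5.1e-05 on day 4. Between 38.7% and 63.4% of probes per sample were not well above background, and a fold against such readings, as for the dimmer KTN1-AS1 probe at day 6, is uncertain in size.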

Other observations

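The classes of small noncoding RNA described here, and their counts, were chosen only after the values had been seen. No enrichment was tested for them. Over all 26762 features, 1136 rose and 868 fell over the mean of both days. Of 9 small nuclear and related structural RNAs, 4 rose and none fell over the mean of both days, RNU6ATAC by 1.64 ± 0.17 log2 units (SE, n = 4 arrays against 4), RNU2-1, a core spliceosomal RNA, by 0.81 ± 0.13, RNU11 of the minor spliceosome by 0.69 ± 0.08 and RN7SK, which holds back transcription elongation, by 0.65 ± 0.10. RN7SL1, also of this class, differed between the control hairpins by more than RNU2-1, RNU11 or RN7SK rose, without passing the test. Of 132 C/D box small nucleolar RNAs, which guide methylation of ribosomal RNA, 19 rose and none fell (median 0.08), and of 94 H/ACA box RNAs, which guide pseudouridylation, 9 rose and 3 fell (median 0.05).

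With hairpin 2 at day 6, 1541 of all 26762 features rose and 1137 fell. Of 21 small Cajal body RNAs, which guide modification of spliceosomal RNAs, 11 rose with it and none fell (median 0.37). With hairpin 1 at day 6, where 2259 features rose and 1626 fell, 2 of these RNAs rose and 5 fell (median 0.04). In the direct comparison, in which 1700 of 26762 features differed, 9 were lower with hairpin 1 and none higher, SCARNA13 by −2.61 ± 0.15 log2 units, SCARNA12 by −1.60 ± 0.14, SCARNA20 by −1.26 ± 0.14 and SCARNA14 by −1.25 ± 0.15 (adjusted p = 7.6e-05 to 0.00125 in limma, n = 2 arrays against 2).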
